A study of Homo sapiens with 2 samples.

How the data were processed

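As labelled, the RNA came from DLD1 cells, an established human colorectal carcinoma line, and was measured on 2 Affymetrix oligonucleotide arrays. Of these, 1 was from untreated cells and 1 from cells given an adenovirus that carries LEF-1. Per the labels, exposure to the virus lasted 48 hours, RNA was extracted on columns, amplified and labelled with biotin, and the untreated cells received no virus. Array processing by the authors used Microarray Suite 5.0, and the deposited values are MAS5 signals, a linear intensity per probe set. A probe set is a group of short probes against 1 transcript region. Each array holds 54675 probe sets, of which 62 are control probe sets. The 2% trimmed mean of the deposited intensity was 500.056 on the DLD1 array and 500.069 on the DLD1+LEF-1 array, so both arrays had been scaled by the authors to a common level. The scaling target, any filter and the detection calls are not given in the sources used here. Rescaling to a common trimmed mean thus changed signals little, by a factor of 0.99979 for DLD1 and 1.0002 for DLD1+LEF-1. The shapes of the distributions still differed. On the DLD1 and DLD1+LEF-1 arrays the 75th percentile was 532.95 and 435.95, and the 98th was 6629.77 and 8126.42.

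Samples were grouped by their titles, and both columns of the table matched a sample. Each group has 1 array, so no spread between cultures could be measured, no test was run between groups and no p-value is given. A single array per group leaves the precision of every value unmeasured. Because the control cells received no virus, an effect of LEF-1 and an effect of infection cannot be told apart in this design.

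Signals were rescaled to the same 2% trimmed mean over the 54613 probe sets that are not controls. Signals below a floor of 119.075, the 50th percentile of both arrays pooled, were set to the floor. The value of a gene is the log2 ratio of its floored signal on the DLD1+LEF-1 array to that on the DLD1 array, positive where the DLD1+LEF-1 array was brighter. Where 1 array lay at the floor, the fold is a lower bound and is given as at least that fold, and the log2 ratio is bounded in the same way. Signals are printed before flooring. Of the non-control probe sets, 41091 were assigned to 1 gene, 1801 to several genes and 11721 to none. Entrez identifiers matched a current symbol in a RefSeq table of assembly GRCh38.p14 for 41037 probe sets, and the other 54 kept the symbol of the array annotation. A gene was represented by its brightest single-gene probe set, passing over probe sets of the cross-hybridising _x_at kind where the gene had another. Of 19775 genes with such a probe set, 14163 were above the floor on at least 1 array and counted as measured. Genes without a single-gene probe set in the annotation used here were not analysed here.

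A gene counted as higher or lower when it differed by at least 2-fold, and counts at 4-fold are given as well. As a stand-in for a missing error, the log2 ratios of the 2 brightest probe sets of a gene were compared. Only probe sets above the floor on both arrays and not of the _x_at kind were used. This measures disagreement between probes on the same pair of arrays and says nothing of the spread between cultures. For each of 26 gene lists, the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, matched in 10 bins of mean signal. A list stood apart when its percentile lay below 2.5 or above 97.5. The percentile describes these 2 arrays and is not a test between groups, because genes are not independent replicates. The lists, the floor, the size rule, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were LEF1, the 12 highest and 12 lowest genes whose brighter signal passed the 75th percentile and whose other probe sets above the floor had the same sign, and up to 5 members of each list with the largest absolute log2 ratio of at least 1. CDH1, VIM, FN1, CDH2, SNAI1, SNAI2, ZEB1, TWIST1, AXIN2, MYC, CCND1, TGFB1, TGFB2, TGFB3 and CTNNB1 were named whatever their value. Any further list member named in the text was chosen after its values were seen. RNA integrity was read from the ratio of 3′ to 5′ signal of the GAPDH and ACTB control probe sets, of bacterial poly-A transcripts that pass through labelling, and of labelled bacterial controls added at hybridisation.

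Alternatives were a floor at the 25th or 75th percentile, signals as deposited, ratios centred on their median, quantile normalization, a lowess trend of the ratio on signal removed with a span of 0.3, the mean over all probe sets of a gene, 50 units added in place of the floor, a 3-fold threshold, lists without shared genes, a list without LEF1 and random lists not matched on signal. The removal of a running median over 51 neighbouring genes and the requirement of at least 2 probe sets past the threshold were added after the data had been seen. For the neighbourhood analysis, also added afterwards, 14120 measured genes were put in the gene order of GRCh38.p14 and cut into 275 windows of 50 genes, and 1000 shuffles of the genes gave the range expected without neighbourhood. Scripts were tested on simulated data with a noise SD of 0.6 for 14163 genes, in which 93% of 200 genes changed 4-fold passed 2-fold in the right direction and 9.29% of unchanged genes passed it. In lists of 30 simulated genes shifted by 0.75, all 20 stood apart, and 0 of 20 lists with no shift did. Simulated genes varied independently, without a floor or shifts shared by related or neighbouring genes. These rates therefore check the scripts and do not give the power or the rate of false calls in the real data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.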

Results

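By the labels, expression was measured in untreated DLD1 colon carcinoma cells and in DLD1 cells 48 hours after adenoviral delivery of LEF-1. LEF-1 is a DNA-binding partner of beta-catenin in Wnt signalling. Whether both arrays hold RNA of 1 cell population stays open: 12 of 23 chromosomes had a median log2 ratio outside the interval of shuffled genes. This question stands beside every gene group below. The study addressed the epithelial-mesenchymal transition (EMT), in which epithelial cells lose their junctions and take on mesenchymal features. Each group held 1 array, so every value below is a single measurement without a replicate error. Of 54613 probe sets that are not controls, 26804 on the DLD1 array and 27807 on the DLD1+LEF-1 array lay above the floor used for ratios. Over all 54675 probe sets, median signal was 114.7 on the DLD1 array and 123.3 on the DLD1+LEF-1 array. The brightest probe sets reached 104631 and 116310, the latter a hybridisation control. The correlation of floored log2 signals between the arrays, taken across probe sets, was 0.881.

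LEF1 itself was brighter on the array labelled DLD1+LEF-1 with 1 of its 3 probe sets. Signal of the probe set that represents the gene was 347.8 in DLD1 and 7144 in DLD1+LEF-1, a 20.5-fold difference and a log2 ratio of 4.36. Another probe set read 2305 and 2230, a log2 ratio of −0.05. The third, dimmer, read 211.2 and 25.4, a log2 ratio of −0.83 or lower. Averaged over its floored probe sets, the log2 ratio of LEF1 was 1.16. Which parts of the transcript these probe sets cover, and which of them the delivered cDNA holds, was not analysed here.

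The 2 arrays differed widely. Among 14163 measured genes, 2016 (14.2%) were at least 2-fold higher and 2573 (18.2%) at least 2-fold lower on the DLD1+LEF-1 array, and 9574 lay within 2-fold. At 4-fold, 538 genes were higher and 715 lower, but this balance depends on the floor and on the scaling. With a floor at the 25th percentile 1321 were higher and 1181 lower, and 253 and 229 at the 75th. Quantile normalization gave 597 higher and 612 lower at 4-fold, and 2247 and 2279 at 2-fold. With the lowess trend removed the counts were 575 and 621 at 4-fold, and 2163 and 2296 at 2-fold. Among the 12 highest genes, KRT23, an intermediate filament gene, was at least 460-fold higher, with signals of 55.2 and 54773. VIM, the mesenchymal intermediate filament vimentin, had signals of 141.9 and 18863, a 133-fold difference, and its second probe set, dim and below the floor in DLD1, gave a log2 ratio of at least 0.34. KRT5, a basal keratin, had a log2 ratio of at least 6.61, CCND2, a D-type cyclin, was at least 106-fold higher, and IGFBP7, a secreted protein that binds insulin-like growth factors, at least 80.4-fold. LGALS1, the lectin galectin-1, was 58.7-fold higher and the calcium-binding S100A2 58.4-fold. DHRS2 and STC2, the latter a secreted glycoprotein, were at least 85.2-fold and 73.2-fold higher, PRF1 at least 70.5-fold and RFLNB at least 55.4-fold. RAP1A had the highest log2 ratio, at least 9.45, but the other probe sets of RAP1A ranged from 0.06 to at least 9.92. Whether the bright RAP1A probe sets read RAP1A transcripts or other RNA, viral RNA included, was not analysed here.

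At the opposite end, AGR2, a protein of the secretory pathway, had signals of 19618 and 20.3 and was at least 165-fold lower on the DLD1+LEF-1 array. ID3 and ID1, inhibitors of basic helix-loop-helix factors, were lower at least 88.6-fold and, for ID1, 45.2-fold. The tetraspanin TSPAN8 was at least 80.3-fold lower, the glutathione S-transferase GSTM3 73.3-fold and SELENBP1 at least 59.4-fold. CMBL was at least 38.2-fold lower with 1 probe set, but a brighter one gave a log2 ratio of −0.19, and the second GSTM3 probe set gave −0.64. RAB27B and RAB25, small GTPases of vesicle transport, were at least 54.2-fold and 52.3-fold lower. RBM47, an RNA-binding protein, was 43.3-fold lower, with another probe set at −4.85, LINC02086 had a log2 ratio of −5.32, and CDH17, an intestinal cadherin, was at least 36.4-fold lower.

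Different probe sets of a gene mostly shared the sign of the difference and less often its size. Within 4227 genes with 2 probe sets above the floor on both arrays, log2 ratios had an SD of 0.603 within a gene and a correlation of 0.655 across genes. Probe sets at the floor on 1 array, as for many of the genes named above, were left out of this comparison. Of 1284 genes whose brighter probe set differed at least 2-fold, 1122 (87.4%) had the same sign in the other probe set and 659 (51.3%) passed 2-fold the same way. Dim genes agreed less. With both mean signals at or below the 75th percentile, 72.8% of 261 such genes shared the sign and 21.5% passed 2-fold the same way. With both above it, the shares were 93.3% and 64.7% of 750. A floor at the 25th percentile gave 3994 genes at least 2-fold higher and 3730 lower, so the balance turned, and a floor at the 75th gave 1174 and 1379.

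**Figure D1:**
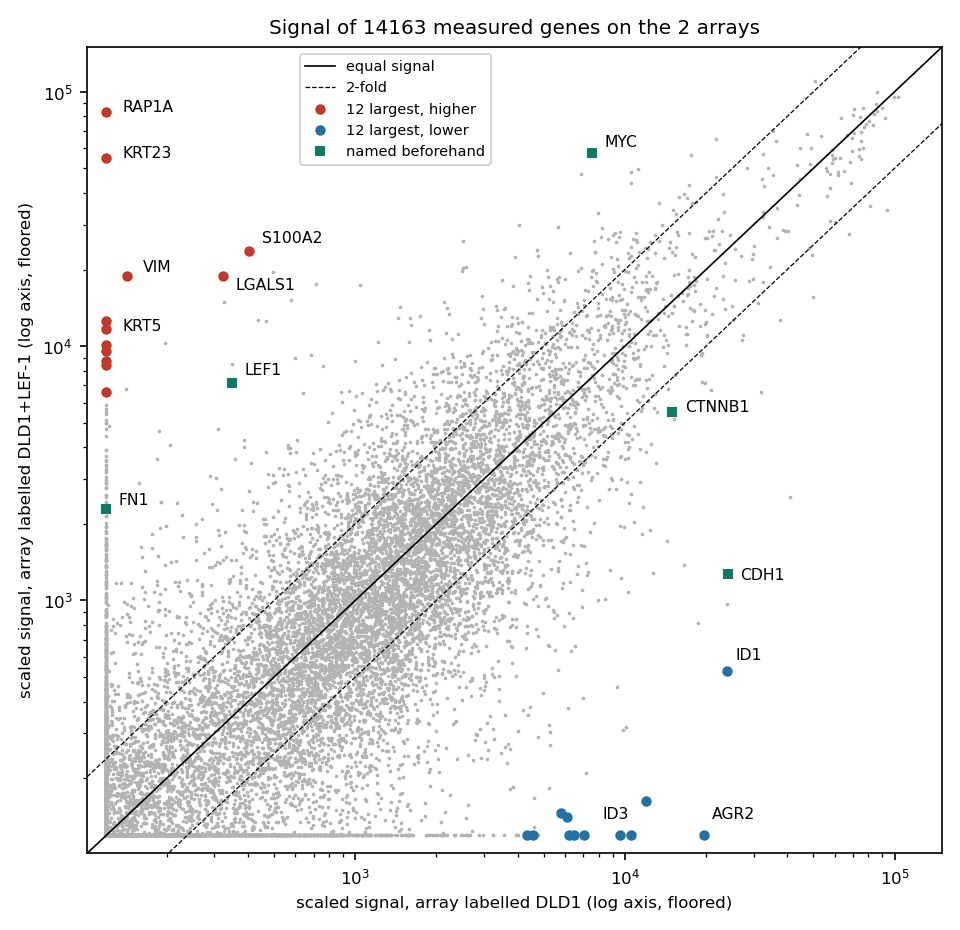
Each point is 1 of 14163 measured genes, with its scaled signal (intensity units, log axes, floored at 119.075) on the DLD1 array on the x axis and on the DLD1+LEF-1 array on the y axis; dashed lines mark 2-fold. KRT23 and RAP1A lie at the floor in DLD1 and at 54773 and 83399 on the other array, and AGR2 lies at the floor on the DLD1+LEF-1 array.

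Some control transcripts separated the arrays by position along the RNA. The 3′ to 5′ signal ratio of GAPDH was 1.52 in DLD1 and 3.88 in DLD1+LEF-1, and that of ACTB was 3.42 and 6.80. For the bacterial dap transcript, carried through labelling, the ratio was 5.86 and 16.1 in 1 pair of probe sets and 4.26 and 16.3 in the other. In 8 pairs of probe sets for the hybridisation controls bioB, bioC, bioD and cre, the log2 change of this ratio ran from −0.18 to 0.22. Of 6 dimmer poly-A pairs, for thr, phe and lys, 5 changed by −0.25 to 0.14 and 1 by 1.69. GAPDH, ACTB and dap thus had relatively weaker 5′ signal on the DLD1+LEF-1 array, a difference in RNA that stands beside every gene group below.

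Epithelial genes were lower as a group, with members past 2-fold in both directions. Of 39 measured epithelial junction, keratin and regulator genes, 16 were at least 2-fold lower, 9 at least 2-fold higher and 14 within 2-fold, with a median log2 ratio of −0.41 at percentile 2.26 of the random lists. CDH1, the E-cadherin of adherens junctions, had signals of 24127 and 1268 and was 19.0-fold lower, and its other probe set gave a log2 ratio of −3.32 or lower. RAB25 was at least 52.3-fold lower, and the tight junction protein gene TJP3 and the protease inhibitor SPINT1 had log2 ratios of −3.09 and −2.98. The epithelial transcription factor ELF3 gave −4.22, but 0.03 and 0.20 with its other probe sets. KRT8 and KRT18, the simple-epithelium keratins, were higher, with log2 ratios of 1.58 and 1.12, as were DSP, a desmosomal plaque gene, at 1.18 and CTNNA1, the alpha-catenin gene, at 1.77, although 1 other CTNNA1 probe set had the opposite sign. TJP1, CLDN1, ESRP1, PARD6B and MUC1 were the other members at least 2-fold higher, at 1.10, 1.31, 1.33, 1.54 and 1.03. The desmosomal genes DSG2, DSC2 and JUP were lower, at −2.35, −2.33 and −2.17. EPCAM, a surface marker of epithelium, was bright on both arrays at 23511 and 21239. With quantile normalization the list no longer stood apart, at percentile 2.76.

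Mesenchymal genes did not move as 1 group. Of 30 measured members, 6 were at least 2-fold higher, 5 at least 2-fold lower and 19 within 2-fold, with a median of 0.25 at percentile 90.7. VIM led with a log2 ratio of 7.05. AXL, a receptor tyrosine kinase, was 19.7-fold higher, S100A4 15.0-fold, and FN1, the matrix protein fibronectin, at least 19.2-fold, with 4 of 5 further FN1 probe sets of the same sign. TPM1, a tropomyosin, was 20.4-fold lower, and the matricellular gene CCN2 had a log2 ratio of −3.45. CDH2, the N-cadherin gene, was below the floor in DLD1, at 59.6, and just above it in DLD1+LEF-1, at 121.4. The list stood apart as higher with a floor at the 75th percentile, with the mean over probe sets, without shared genes and with the neighbourhood median removed. Among 12 measured EMT transcription factors, 3 were at least 2-fold higher, 3 lower and 6 within 2-fold, with a median of 0.43 at percentile 92.2. SNAI2 was at least 3.78-fold higher with signals of 61.4 and 450.3, and MSX1 4.71-fold. SNAI1 and ZEB1 were below the floor in DLD1 and dim in DLD1+LEF-1, with log2 ratios of at least 0.69 and 0.96, and TWIST1 lay below the floor at 50.8 and 73.3. SOX9 was 9.48-fold lower, MSX2 at least 8.35-fold and TCF4 at least 6.63-fold.

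**Figure D2:**
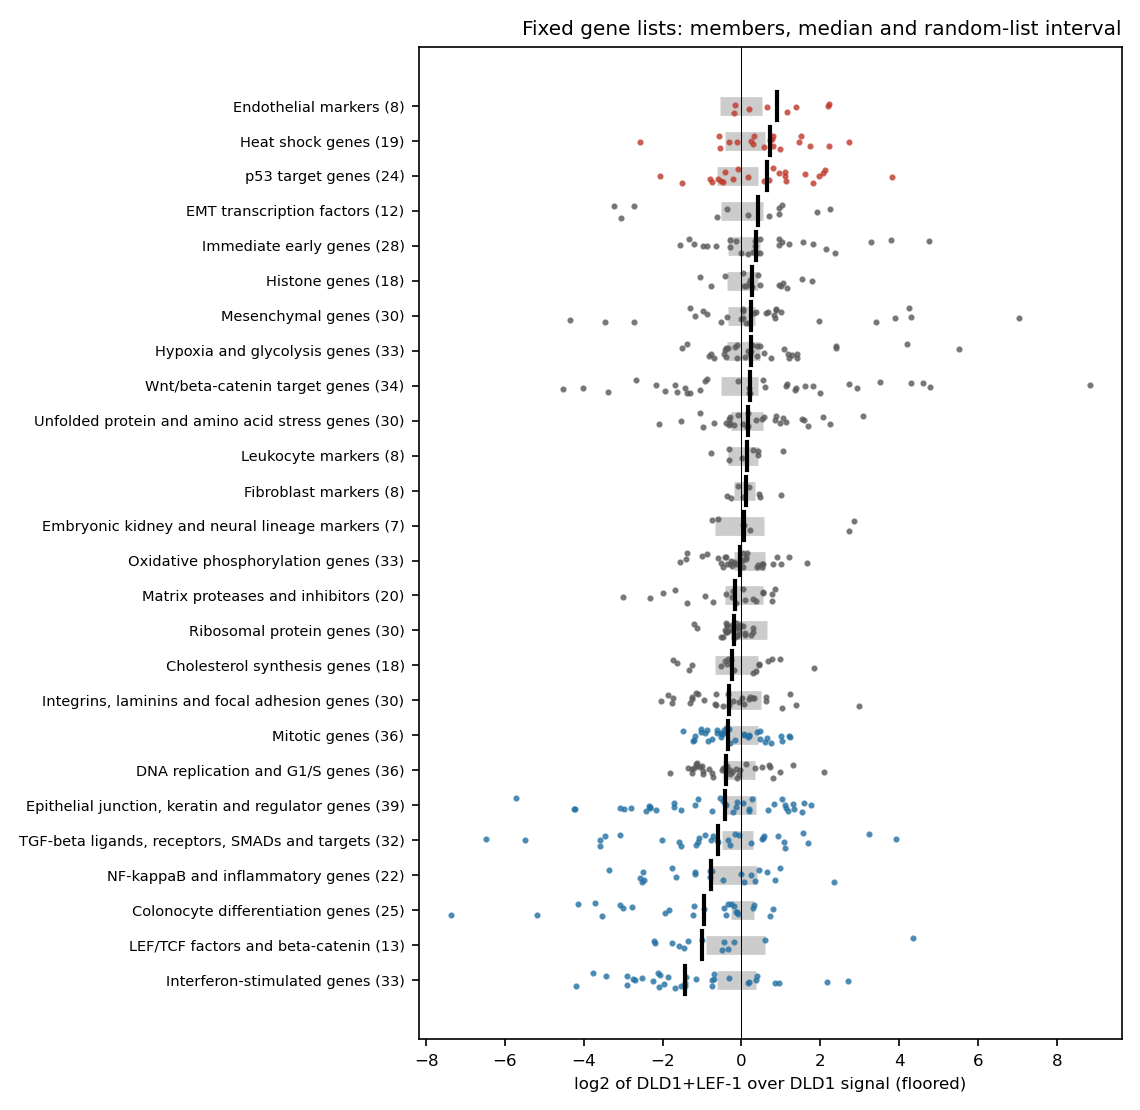
Log2 ratio of DLD1+LEF-1 over DLD1 signal (x axis) for the measured members of the 26 gene lists (rows, number of measured members in brackets). Points are genes, black ticks are list medians, grey bars hold 95% of random lists, and colour marks the 3 lists that stood apart as higher (red) and the 7 as lower (blue).

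Wnt target genes split in both directions. Of 34 measured targets, 14 were at least 2-fold higher, 12 at least 2-fold lower and 8 within 2-fold, with a median of 0.21 at percentile 87.9. MYC was 7.61-fold higher, at 7538 and 57392, and CCND1, a D-type cyclin, 3.54-fold. APCDD1 was at least 27.6-fold higher, the adhesion molecule L1CAM at least 24.2-fold and the secreted Wnt antagonist DKK4 at least 19.6-fold. AXIN2, a negative feedback gene of the pathway, was 2.06-fold lower, and the stem cell receptor LGR5, at the floor in DLD1+LEF-1, gave −3.38 or lower. BMP4, a growth factor of the TGF-beta superfamily, was 22.9-fold lower. The list of the pathway's nuclear factors was lower. Of 13 measured LEF/TCF factors and cofactors, 1 (LEF1) was at least 2-fold higher, 6 were at least 2-fold lower and 6 within 2-fold, with a median of −0.998 at percentile 1.33. CTNNB1, which encodes beta-catenin, had signals of 14977 and 5491, a log2 ratio of −1.45, and its other probe sets gave −0.19 and, as a bound, −2.85 or lower. TCF7L2, the main intestinal TCF factor, gave −1.76, and its other probe sets above the floor on both arrays ran from −2.34 to −1.33. CTNNBIP1 was at least 4.66-fold lower, and TLE1 and TLE4 gave −2.20 and −1.58, although TLE1 probe sets ran from −2.88 to at least 0.80. TLE3 gave 0.60. A floor at the 25th percentile put this list at percentile 2.92, a removed lowess trend at 2.6 and a removed neighbourhood median at 3.27.

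The list of TGF-beta ligands, receptors, SMADs and targets was lower. It pools activators, inhibitors and targets of the pathway, so its median gives no direction of signalling. Of 32 measured members, 12 were at least 2-fold lower, 6 at least 2-fold higher and 14 within 2-fold, with a median of −0.60 at percentile 0.7. The SMAD targets ID1 and ID3 led, followed by ID2, which was 12.1-fold lower. SMAD4, the common mediator of the pathway, had signals of 1429 and 5.30 and a log2 ratio of −3.59 or lower. PMEPA1, a TGF-beta-induced inhibitor of the pathway, was 15.2-fold higher. The ligand TGFB1 gave a log2 ratio of 0.55 but −1.54 or lower with its second probe set, and averaged over both floored probe sets it was −0.50. TGFB2 and TGFB3 gave −1.07 and −0.78. Genes next to SMAD4 along the chromosome were lower too, and with the neighbourhood median removed the list lay at percentile 9.73.

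Genes that lie near each other in the genome differed together. In 275 windows of 50 neighbouring measured genes, the SD of window medians was 0.295, against at most 0.186 in 1000 shuffles of the genes. Window medians lay below the shuffled interval in 17 windows and above it in 24, and the shuffle with most had 9 outside. In the window that holds SMAD4 the median log2 ratio was −1.26, 45 of 50 genes were below 0, 31 were at least 2-fold lower and 0 at least 2-fold higher. RAB27B and TCF4 lie in this window, and HERC6, SPINT1 and TIMP4 lie in other low windows, while PMEPA1 and L1CAM lie in high ones. ID1, ID2 and CDX2 also lie in high windows although they were lower, and of 8 named genes past 2-fold in high windows 3 were lower, while all 11 in low windows were lower. Of 134 named genes past 2-fold, 115 lie in windows inside the shuffled interval, among them CDH1, VIM and MYC.

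**Figure D3:**
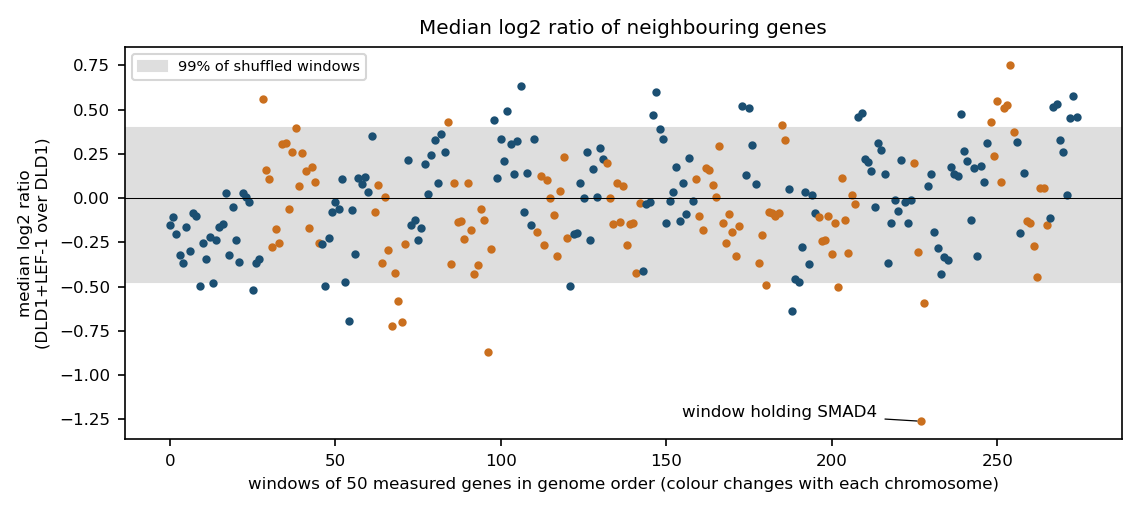
Median log2 ratio of DLD1+LEF-1 over DLD1 signal (y axis) in windows of 50 measured genes in genome order (x axis), with the 99% interval of shuffled windows in grey. The window holding SMAD4 is lowest, at −1.26.

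Interferon-stimulated genes had the lowest list median with the floor used. Of 33 measured members, 20 were at least 2-fold lower, 2 at least 2-fold higher and 11 within 2-fold, with a median of −1.44 below the medians of all 10000 random lists. With a floor at the 75th percentile the median was −0.71. The antiviral 2′-5′-oligoadenylate synthetase genes OAS3 and OAS1 were at least 18.4-fold and 7.47-fold lower, and the RNA sensor IFIH1 at least 7.44-fold. HERC6 was at least 13.5-fold lower, and PARP9 at least 10.8-fold with 1 probe set and at 0.05 on the log2 scale with the other. IFI27 and IFITM1 were higher, with log2 ratios of at least 2.71 and of 2.16. NF-kappaB and inflammatory genes were lower as well, with 9 of 22 measured members at least 2-fold lower, 1 at least 2-fold higher and a median of −0.77 at percentile 1.94. Of the chemokine genes, CXCL5 was 10.2-fold lower, CXCL3 5.52-fold, CCL20 at least 5.90-fold and CXCL1 at least 5.76-fold, and the kinase IRAK2 was at least 5.66-fold lower. This call was lost with a floor at the 75th percentile, at percentile 30.9, with the neighbourhood median removed, at 23.7, with a removed lowess trend and with the offset in place of the floor.

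Colonocyte differentiation genes were lower without exception past 2-fold. Of 25 measured members, 12 were at least 2-fold lower, 0 at least 2-fold higher and 13 within 2-fold, with a median of −0.96 below all random lists. After AGR2 and CDH17, CDX2, the homeobox factor of intestinal identity, was at least 17.6-fold lower with signals of 2095 and 78.6. The second, dimmer CDX2 probe set gave a log2 ratio of −0.77. The peptidase DPP4 was at least 13.2-fold lower and the trefoil peptide TFF1 11.7-fold. LCN2 was bright on both arrays, at 21478 and 15731.

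Mitotic genes were lower as a list, and DNA replication genes did not stand apart. Of 36 measured mitotic genes, 6 were at least 2-fold lower, 4 higher and 26 within 2-fold, with a median of −0.35 at percentile 1.99. MKI67, KIF11 and ECT2 gave log2 ratios of −1.48, −1.22 and −1.21, MKI67 with another probe set at 0.57, and AURKA and NDC80 gave 1.22 and 1.21. The mitotic list no longer stood apart under 4 of the alternatives fixed beforehand, with percentiles from 2.52 to 4.53, and with the neighbourhood median removed its median was −0.023 at percentile 29.3. Of 36 measured DNA replication genes, 9 were at least 2-fold lower and 2 higher, with a median of −0.38 at percentile 5.46. The licensing factor CDC6 was 4.24-fold higher and MCM7 2.47-fold, while E2F2, ORC1 and TYMS gave −1.81, −1.35 and −1.25. Target genes of p53 were higher, with 9 of 24 measured members at least 2-fold higher, 2 lower and a median of 0.64 at percentile 99.8. PHLDA3 had a log2 ratio of at least 3.81, and the cell cycle inhibitor CDKN1A was 4.32-fold higher, SESN2 4.23-fold and GADD45A 3.93-fold, and TP53I3 was 4.21-fold lower. With the mean over probe sets the median of the p53 list was 0.14, at percentile 85.9.

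Adhesion and matrix protease genes did not stand apart. Of 30 measured integrin, laminin and focal adhesion genes, 9 were at least 2-fold lower and 4 higher, with a median of −0.32 at percentile 5.49. ACTN1, an actin crosslinker, was 7.96-fold higher, and LAMB2, a laminin chain, was 4.09-fold lower. PTK2, VCL and ITGB8 gave −1.86, −1.75 and, as a bound, −1.74, and each of these had another probe set with a ratio of the opposite sign. Of 20 measured matrix proteases and inhibitors, 5 were at least 2-fold lower and 0 higher, with a median of −0.17 at percentile 14.1. These were TIMP4, MMP15, SERPINB5, ADAM10 and ADAM9, lower by 7.98-fold, 4.97-fold, 3.96-fold, 3.23-fold and 2.62-fold.

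Among stress and signalling lists, heat shock genes stood apart as higher. Of 19 measured heat shock genes, 5 were at least 2-fold higher, 1 lower and 13 within 2-fold, with a median of 0.71 at percentile 98.97. The co-chaperones FKBP4 and CHORDC1 were 6.66-fold and 4.69-fold higher, HSPA2 and DNAJB6 gave 1.75 and 1.52, and DNAJB4 was 5.99-fold lower. HSPA1A, HSPA1B and HSPA8 had no single-gene probe set and were not measured. Within 2-fold, DNAJB1 and BAG3 gave −0.56 and −0.55, and HSPB1, HSP90AA1 and HSPD1 gave 0.30, 0.81 and 0.81. The heat shock call was lost with a removed lowess trend, at percentile 95.6, and with the mean over probe sets, at 86.4. Of 28 measured immediate early genes, 9 were at least 2-fold higher and 3 lower, with a median of 0.37 at percentile 92.8. The AP-1 subunit FOSL1 was 26.9-fold higher, EGR3 at least 13.8-fold, ATF3 9.73-fold, JUN 5.16-fold and IER3 4.45-fold, JUN with another probe set at −0.43 or lower. Of 30 unfolded protein and amino acid stress genes, 8 were at least 2-fold higher and 3 lower, with a median of 0.16 at percentile 56.3. CTH, DDIT3 and ASNS gave log2 ratios of 3.08, 2.24 and 1.68, and the chaperone CALR gave −2.08. The other CALR probe sets, brighter and of the _x_at kind, gave −0.54 and −0.61. Of 33 measured hypoxia and glycolysis genes, 10 were at least 2-fold higher and 2 lower, with a median of 0.24 at percentile 80.9. The glucose transporters SLC2A3 and SLC2A1 were 46.0-fold and 5.32-fold higher, ANKRD37 18.3-fold and ENO2 5.29-fold, and the oxygen sensor EGLN1 was 2.85-fold lower.

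Lists of metabolic, ribosomal and histone genes did not stand apart. Of 18 measured cholesterol synthesis genes, 1 was at least 2-fold higher and 4 lower, with a median of −0.23 at percentile 36.8, led by STARD4 at 1.85 and HMGCS1 at −1.73. SREBF2, HSD17B7 and TM7SF2 gave −1.65, −1.33 and −1.24, SREBF2 with another probe set at −0.18. Of 33 oxidative phosphorylation genes, 3 were higher, 3 lower and 27 within 2-fold, with a median of −0.03 at percentile 14.2. NDUFV1 and NDUFS1 gave 1.67 and 1.22, and ATP5F1C, NDUFB8 and ATP5F1A gave −1.55, −1.40 and −1.37. The other ATP5F1A probe set, dim and below the floor in DLD1, had the opposite sign, at 0.49 or higher. The other 3 probe sets of ATP5F1C, all brighter, gave 0.18 to 0.27, and the other 2 of NDUFS1 0.75 and, dim, −0.28 or lower. Of 30 ribosomal protein genes, 28 lay within 2-fold and RPS27 and RPL24 gave −1.19 and −1.12, with a median of −0.18 at percentile 2.5, on the boundary. With the lowess trend removed the ribosomal median was −0.55 at percentile 0.23, and a floor at the 75th percentile or signals as deposited also put the list apart as lower. Of 18 measured histone genes, 5 were higher and 1 lower, with a median of 0.26 at percentile 83.6, or 0.58 at percentile 99.1 with the neighbourhood median removed. H2BC4, H3C8, H4C8 and H2BC21 gave 1.80, 1.53, 1.15 and 1.05, and H2AC4 gave −1.05 or lower.

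Markers of other cell types were mostly dim on both arrays. Of 8 measured fibroblast markers all lay within 2-fold, with a median of 0.11 at percentile 53.2. Of 8 leukocyte markers, 7 lay within 2-fold, and CD79A gave 1.05, with a median of 0.15 at percentile 62.4. Of 8 endothelial markers, 4 were at least 2-fold higher, with a median of 0.90 at percentile 99.9. EGFL7, FLT1, PECAM1 and TEK reached signals of 554.9, 727.0, 310.4 and 264.1, and the other 2 FLT1 probe sets above the floor gave −0.19 and −0.11. With the mean over probe sets, the endothelial list lay at percentile 97.4. Of 7 embryonic kidney and neural markers, 2 were higher, WT1 at least 7.24-fold and HOXC10 6.58-fold, with a median of 0.07 at percentile 55.7.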

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

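All tests of explanations in this part were chosen after the result they bear on had been seen. Probe sets outside the gene comparisons also carried large differences. Among 5023 probe sets above the floor that no gene was assigned to, 54 (1.08%) were at least 4-fold higher on the array labelled DLD1+LEF-1 and 101 (2.01%) at least 4-fold lower. Their highest floored log2 ratio was 9.05. Among 1259 probe sets above the floor that match several genes, 64 (5.08%) were at least 4-fold higher and 49 (3.89%) lower. For comparison, the shares among 26376 single-gene probe sets above the floor were 2.93% and 4.38%, so unnamed probe sets passed 4-fold less often.

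Control probe sets, which no comparison of genes used, showed weaker 5′ signal on the DLD1+LEF-1 array, with a log2 change of 1.35 in the 3′ to 5′ ratio of GAPDH. Degradation of the cell RNA before bacterial transcripts were added would leave their ratio within 0.5, but the ratio of dap was higher by 1.46 in 1 pair of probe sets and by 1.94 in the other, which argues against it as the whole cause. Shorter labelled RNA from the labelling of the DLD1+LEF-1 sample would raise the ratio in all labelled pairs: the lowest change among 4 bright pairs was 0.99, and among 8 hybridisation pairs the largest absolute change was 0.22. Of 6 dimmer poly-A pairs, however, 5 changed by −0.25 to 0.14 and only 1, for phe, by 1.69, although the 5′ signals of 1 thr pair, 396.6 and 282.9, were about as bright as those of dap on the DLD1+LEF-1 array, 303.1 and 292.2. These pairs disagree, so labelling length remains open, as does degraded cell RNA for a part of the GAPDH and ACTB change, and no biological explanation was tested.

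LEF1 probe sets disagreed by at least 5.19 on the log2 scale. Ordinary disagreement between probe sets of a gene would make so wide a range common among genes that differ as much. Of 15 other genes with 3 probe sets above the floor and as large a ratio in 1 of them, 3 (20%) had a range as wide, so ordinary disagreement remains open, with too few such genes to decide. A vector cDNA that lacks the sequence under the other probe sets also remains open and was not tested.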

How the results depend on the processing

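Directions held for every named gene past 2-fold and for every list that stood apart, under all the alternatives run. For single genes this was largely fixed beforehand: other floors, the offset, signals as deposited and centring cannot reverse a ratio past 2-fold. Quantile normalization, the lowess trend, the neighbourhood median and the mean over probe sets could have done so. The mean could not for the highest and lowest genes, chosen for probe sets of the same sign. TGFB1, within 2-fold, changed sign with the mean over probe sets, at −0.50. Of the recomputed list calls, 257 were the same, 18 were lost and 9 were gained, with lists that did not stand apart counted too. Named genes moved by less than the spread between probe sets in 1070 cases and by more in 165, mostly genes at the floor. The median log2 ratio of all genes stayed between −0.10 and 0.04. Of the lists that stood apart, only the interferon and colonocyte lists did so under every alternative run for them, both as lower. Dim genes depend on the signal taken as background: higher floors remove them and shrink their ratios, which by construction moves the counts. Where nothing else is said, the cause was not tested. The neighbourhood correction and the rule of 2 probe sets were chosen after seeing the data.

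Floors at the 25th and 75th percentile gave 3994 and 1174 genes at least 2-fold higher, 1321 and 253 at least 4-fold higher, and 1181 and 229 at least 4-fold lower. They gave 3730 and 1379 genes at least 2-fold lower, so the balance turned at the 25th percentile. A 3-fold threshold left 927 higher and 1235 lower, and a need for 2 probe sets left 569 higher and 913 lower of 6814 genes that have 2. LEF1 gave 1.16 as a mean over probe sets.

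With the floor at the 25th percentile the LEF/TCF median was −0.74. At the 75th it was −0.30 for NF-kappaB, −0.35 for mitotic genes, 0.81 for mesenchymal genes and −0.18 for ribosomal genes, the latter 2 now apart. Quantile normalization gave −0.39 for epithelial and −0.34 for mitotic genes. The lowess trend removed gave −0.77 for LEF/TCF, −0.51 for NF-kappaB, −0.36 for mitotic, 0.46 for heat shock and −0.55 for ribosomal genes, the last now apart. The mean over probe sets gave 0.14 for p53 targets, 0.31 for heat shock, 0.52 for endothelial and 0.30 for mesenchymal genes, the last now apart, and left 1 list higher. An offset of 50 gave −0.64 for NF-kappaB. Unmatched random lists ended the mitotic call at −0.35. Without shared genes the mesenchymal median was 0.68, apart. The ribosomal list shares no gene, so its median stayed −0.18 and only redrawn random lists took it from percentile 2.5 to 2.3, and signals as deposited left it at −0.18 and percentile 2.43. With the neighbourhood median removed, 5 lists were higher and 3 lower: mesenchymal at 0.44 and histone genes at 0.58 now stood apart, and LEF/TCF at −0.77, TGF-beta at −0.32, NF-kappaB at −0.33 and mitotic genes at −0.023 did not.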

Other observations

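Gene families picked by name after the values were seen, with all the tests of explanations below also chosen afterwards, showed several further differences. Members were matched by patterns of the gene symbol, which do not take in every member of a family. Of 10 measured S100 genes, which encode small calcium-binding proteins, 7 were at least 2-fold higher on the array labelled DLD1+LEF-1 and 1 lower, or 6 higher with the lowess trend removed. S100A11 was 6.90-fold higher, with signals of 6866 and 47393, and S100A14 was 34.1-fold lower. All 5 measured metallothioneins, proteins that bind zinc and copper, were at least 2-fold higher, from 1.00 for MT1E to 1.85 for MT1X on the log2 scale, and 4 of the 5 under quantile normalization or with the lowess trend removed. Of 13 measured glutathione S-transferases, 8 were at least 2-fold lower and 0 higher, or 7 lower under the same alternatives, among them GSTO2 at −3.79, GSTM4 at −2.89 and GSTM2 at −2.34. Members of a family are not independent observations: MT1H and MT1X, for example, are next to each other in gene order. Whether probe sets of related members read each other's transcripts was not analysed here.

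Keratins and homeobox genes, families that differ between kinds of epithelium and along the body axis, held genes past 2-fold in both directions. Of 22 measured keratins, 7 were at least 2-fold higher and 2 lower, and other scalings gave 6 to 8 higher. KRT74 and KRT13 were at least 21.8-fold and 5.90-fold higher beside KRT5 and KRT23, while KRT20 gave −3.09 or lower. Of 23 measured HOX genes, 7 were at least 2-fold higher and 4 lower, with a median of 0.018 at percentile 63.2 of random lists. All were of the HOXB, HOXC and HOXD clusters. HOXB6, HOXB7 and HOXB9 were lower, at −2.32, −1.96 and −1.36, HOXB2 was at least 12.1-fold higher, and HOXC4 and HOXC10 gave 1.57 and 2.72. Tetraspanins, also examined, did not stand apart: of 18 measured, 2 were at least 2-fold higher and 6 lower, with a median of −0.22 at percentile 33.9.

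Neighbouring genes differed together across the genome, and 12 of 23 chromosomes had a median log2 ratio outside the shuffled interval, against at most 2 in 1000 shuffles. With trends of the ratio on signal and on gene length removed, 13 chromosomes lay outside, against at most 3 in shuffles, which argues against these trends as the cause. What stays open, as a hypothesis, is that the array labelled DLD1+LEF-1 may hold RNA of a cell population with another set of chromosome copies, a subline or another line. Some shifts ran along a whole chromosome or a long part of it. All window medians of chromosome 20 were positive, from 0.09 to 0.75. Those of chromosome 18 read 0.20, −0.30, −1.26 and −0.59 in gene order, while chromosome 19 held windows of both signs. A response to LEF-1 or the virus would have to be shared by neighbouring genes over such lengths. That was not tested and stays open, and neither DNA nor a second array was analysed here. Log2 ratios, clipped at −2 and 2, had a correlation of 0.045 between measured genes 50 places apart, against at most 0.029 in shuffles. Among genes within 2-fold, a choice that itself truncates the ratio, it was weaker, at 0.027 with a shuffle SD of 0.011 and a highest shuffle of 0.036. At 100 places it was 0.033 among these genes, with a shuffle SD of 0.011 and a highest shuffle of 0.044. Lying below the highest of 1000 shuffles does not show that the pattern is absent there.

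Values of 2 further genes, also chosen after they were seen, are given without explanation. Signals of the 4 SMAD4 probe sets above the floor were 1429 and 5.30, 928.9 and 101.9, 352.8 and 118.6, and 121.0 and 63.4, each lower on the DLD1+LEF-1 array. MSH6, a mismatch repair gene known to carry a truncating mutation in DLD1, was higher with both of its probe sets above the floor, at 1172 and 3943 and at 137.3 and 1280.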
